A study of Mus musculus with 26 samples.

How the data were processed

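Livers of 3 mouse groups were measured: C57BL/6J mice on normal diet (wild type), C57BL/6J mice on high-fat diet, and B6.V-Lepob/J mice on normal diet (ob/ob, which lack leptin and become obese). Per the labels' protocols, tissue was homogenised in hypotonic buffer, a cytoplasmic supernatant and a salt extract of the nuclei were made, and each extract was first passed over beads with control IgG and then over beads with an antibody against hnRNPK. RNA was eluted from the beads and sequenced beside total liver RNA, with libraries made with a TruSeq RNA kit, per the labels' protocols. Strandedness is not given in the sources used here. Total RNA is not the input of either extract, so a difference between immunoprecipitated (IP) and total RNA includes the fractionation as well as the precipitation.

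The deposited tables hold 1 row per transcript. Their estimated counts (expected counts) and TPM were made by the authors with RSEM 1.2.8. The other tools named are bcl2fastq, TopHat2 2.0.10, Bowtie2 2.1.0 and SAMtools, with genome build mm10, per the submitters' processing notes, which give no role or order. Each of the 26 tables listed the same 59121 transcripts in 31469 numbered gene clusters, of which 19320 had a single isoform. The deposited TPM values were not used for any test, because they keep no depth. The deposited transcript length, in nucleotides, was used to weigh length. RSEM divides reads among overlapping or similar transcripts, so clusters that share sequence or overlap are uncertain, as are antisense pairs.

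The deposited files pair no transcript or cluster with a gene symbol, and no table used here links these identifiers to symbols. Clusters are therefore named by the identifier of their most counted isoform, and at most 2 that were higher and 2 that were lower are named per comparison. The rule was fixed before the data were examined and asked for more genes, with symbols, and for hnRNPK and list members, which could not be followed. What was kept of it is: clusters past the threshold, with a mean log2 CPM of at least 1 and the same direction in every unit or unit pair, ranked by log2 fold change. Gene lists, cell type markers, the transcript of hnRNPK itself and the base composition of transcripts were planned and could not be analysed without symbols.

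Expected counts were summed per cluster and rounded to whole numbers. Total RNA had 2 libraries for each replicate number, told apart by a second number in the titles. They were taken as runs of the same RNA and summed to 1 unit, giving 18 units with 2 per group, but the labels do not say so. The libraries of a pair had Pearson's r of 0.997 to 0.999 on the log2 scale, while their chi-square per degree of freedom was 2.19 to 86.4, above counting noise and highest in ob/ob (25.9 and 86.4). The labels do not say that replicates were separate animals, so p-values measure only the spread between these samples, which may be technical. The IgG libraries, 1 per compartment from mixed mice, enter no edgeR or DESeq2 test. They enter the length relations, whose permutations shuffle clusters, so those p-values do not measure the spread between IgG libraries. Their label for molecule type reads as hnRNPK-bound RNA while their titles say IgG, and the titles were followed.

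Comparisons used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with limma 3.58.1, TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. Total RNA comparisons were fitted on the 6 total RNA units, and IP comparisons and their differences between mouse groups on all 18 units with a mean per group. IP comparisons average the 3 mouse groups with equal weight. Fold changes carry a standard error derived from the test, which gives none itself. It is the absolute log2 fold change divided by the square root of the F value. Levels are CPM with TMM scaling over all units and IgG libraries. Where a side had 0 counts, the bound uses a floor of 3 counts summed over that side on the CPM scale by library size. Other ratios of summed counts have an exact 95% binomial interval, and shares have a 95% Wilson interval, except those of clusters above IgG or in the same direction, which have exact binomial ones. Total counts were 25597307 to 41731910 per total RNA library, 5336060 to 12068891 per IP library, 3116786 for nuclear IgG and 338469 for cytoplasmic IgG, which leaves clusters of low abundance poorly measured in the last. Floors and the intervals of counts cover counting error only. Intervals on shares of clusters take clusters as independent and do not cover the spread between IP or IgG libraries. IP was set against IgG on log2 CPM with a prior count of 1. Length relations are Spearman's rho across clusters with 100000 permutations, two-sided.

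The steps were tested on simulated counts with 200 changed clusters. These were drawn only from clusters with an average log2 CPM over 1, so the recovery does not cover clusters of lower abundance. For ob/ob against wild-type total RNA (15487 clusters), 69% of 2-fold and 98% of 4-fold changes were recovered with 16 false calls. For cytoplasmic IP against total RNA (13516 clusters), 85% and 100% were recovered with 9 false calls, and for nuclear IP 92% and 99% with 8. With only 200 changed clusters, the simulation meets the assumption of TMM scaling that most clusters are unchanged. Most clusters were called in the real IP comparisons, so the simulation does not test the scaling there. Alternatives were DESeq2 1.42.0, its size factors, library size only, no filter, a filter of 5 CPM in 2 units, single runs, runs as replicates, other sets of units, a replicate block, a 2-fold test, each mouse group alone and each unit left out. The remaining scripts used Python 3.11.15.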

Results

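RNA bound to hnRNPK, a heterogeneous nuclear ribonucleoprotein that binds RNA, was sequenced from cytoplasmic and nuclear extracts of mouse liver together with total liver RNA. The design asks which RNAs are held by hnRNPK in each compartment, and whether this differs between wild-type mice on normal diet, wild-type mice on high-fat diet and leptin-deficient ob/ob mice. There were 26 libraries: 12 of total RNA, 6 cytoplasmic IP, 6 nuclear IP and 2 of control IgG. The files do not pair transcript identifiers with gene names, so clusters of transcripts are named by identifier.

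Total RNA libraries held 25597307 to 41731910 counts, cytoplasmic IP libraries 8834063 to 12068891 and nuclear IP libraries 5336060 to 10581089. The cytoplasmic IgG library held 338469 counts and the nuclear IgG library 3116786. A single cluster, singled out after its values were seen, was the most counted in every IP library. It took 12.2% to 28.8% of the counts in cytoplasmic IP and 18.6% to 41.2% in nuclear IP, against 0.876% to 5.14% in total RNA, where the median was 1.36%. The 5.14% came from the first library of ob/ob replicate 1. The second library with that replicate number had 1.22%, and the next highest library had 3.38%. It was also the most counted cluster in IgG, with 17.4% (95% Wilson interval 17.2 to 17.5) in the cytoplasm and 16.5% (16.4 to 16.5) in the nucleus.

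**Figure D1:**
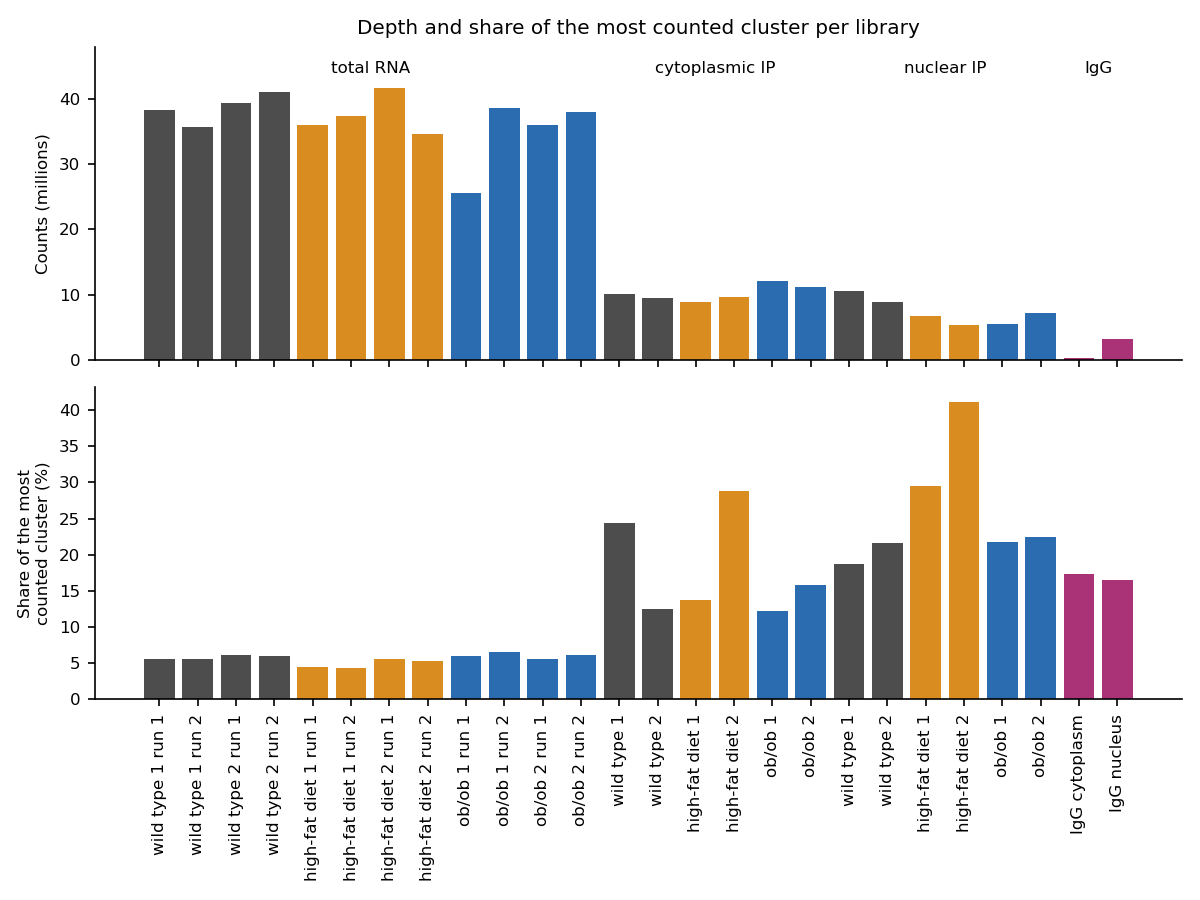
Total counts per library (top, on the scale printed on the axis) and the share of counts taken by its most counted cluster in percent (bottom), for every library, coloured by mouse group. Total RNA libraries lie between 25597307 and 41731910 counts, and the cytoplasmic IgG library is the shallowest at 338469.

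Between units of the same mouse group, Pearson's r of log2 CPM across clusters was 0.976 to 0.991 in total RNA, 0.945 to 0.969 in cytoplasmic IP and 0.928 to 0.956 in nuclear IP. The lowest total RNA value belonged to the wild-type pair. Wild-type total RNA replicate 1 had r of 0.987 and 0.989 with the high-fat diet units, higher than with its own replicate 2 (0.976). Clusters are not independent replicates, and these coefficients describe likeness only.

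Total RNA of ob/ob and wild-type livers was compared to find transcripts that differ with leptin deficiency. Of 15487 clusters tested, 244 passed the threshold, 106 higher and 138 lower in ob/ob. Cluster uc008xyp.2 rose from 0.431 ± 0.272 CPM (SD, n = 2) in wild type to 34.9 in ob/ob, where its units had 26.4 and 43.4 CPM, a log2 fold change of 6.40 ± 0.49 (SE, edgeR adjusted p = 0.010). Cluster uc008qvw.2 rose from 0.227 ± 0.202 to 5.37 ± 2.29 CPM, with an adjusted p of 0.044 from the same edgeR test. Cluster uc008tai.2 fell from 1508 ± 790 CPM to 1.74 ± 0.45, a log2 fold change of -9.66 ± 0.58 (edgeR adjusted p = 0.0064). Cluster uc012dfi.1 fell by 8.32 ± 0.51 on the log2 scale, with the same adjusted p. Among the 244 clusters, the median absolute log2 fold change was 1.27. Without wild-type replicate 1 the log2 fold change was 7.29 for uc008xyp.2 and 6.08 for uc008qvw.2. Without wild-type replicate 2 it was 3.89 for uc008qvw.2 and -9.04 for uc008tai.2, and without ob/ob replicate 2 it was -8.93 for uc012dfi.1. No cluster passed when either ob/ob replicate was left out, 3221 passed without wild-type replicate 1 and 286 without wild-type replicate 2. By library size only 91 passed, 39 higher and 52 lower, and uc008qvw.2 was no longer called (edgeR adjusted p = 0.058). DESeq2 called 2129 clusters. The 2 libraries with the same replicate number were summed, and 5777 clusters passed with each library as its own replicate. The labels do not say which holds.

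High-fat diet was compared with normal diet in total RNA of wild-type mice. With edgeR, 0 of 15487 clusters passed the threshold. At an unadjusted p under 0.05 there were 1527 clusters, and DESeq2 called 313. With each library as its own replicate 2001 passed. Without wild-type replicate 1, 1175 clusters passed, and without wild-type replicate 2, 3 passed. The ob/ob and high-fat diet comparisons use the same wild-type libraries. Pearson's r of their fold changes across clusters was 0.592, against 0.502 in simulations of unchanged groups against shared controls. The covariance was 0.236 against 0.0766 simulated. With ob/ob set against 1 wild-type unit and high-fat diet against the other, the covariance was 0.189 or 0.106 and r 0.316 or 0.209, each resting on single wild-type units. The first way 57 calls were higher in both, 45 lower in both and 38 opposite, where independent lists would share 4.37 and 6.63. The second way 1 was higher in both, none lower and none opposite. Part of the excess may come from the shared controls. Against both wild-type units no call was shared, and independent lists would share 0, since high-fat diet had no call with edgeR. The simulations shared a mean of 0.15 higher and 0 lower clusters.

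Total RNA of ob/ob livers was also compared with that of high-fat diet livers, which contrasts the 2 obesity models directly. Here 76 clusters passed, 19 higher and 57 lower in ob/ob. Cluster uc008xyp.2 rose again, from 0.410 ± 0.059 CPM (SD, n = 2) in high-fat diet, with a log2 fold change of 6.45 ± 0.49 (SE, edgeR adjusted p = 0.0096). Cluster uc009qaq.1 was higher by 3.20 ± 0.23 on the log2 scale. Cluster uc029uus.1 was lower, with a log2 fold change of -7.73 ± 0.41, and so was uc012dfi.1, with -7.55 ± 0.50, at the same adjusted p. These 2 lower clusters have adjacent cluster numbers, 18954 and 18955, so their calls may not be independent. The count was 0 without either ob/ob replicate. It was 7 without high-fat replicate 1, all lower, and 12 without high-fat replicate 2, 1 higher and 11 lower. Clusters uc008xyp.2 (edgeR adjusted p = 0.13 and 0.12) and uc009qaq.1 (0.062 and 0.087) were not called without high-fat replicate 1 or 2, nor was uc012dfi.1 without replicate 1 (0.054). It was 49 by library size only, 12 higher and 37 lower, 1433 with DESeq2 (591 higher, 842 lower) and 4885 with each library as its own replicate. The log2 fold change of uc012dfi.1 was -8.15 without ob/ob replicate 2.

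**Figure D2:**
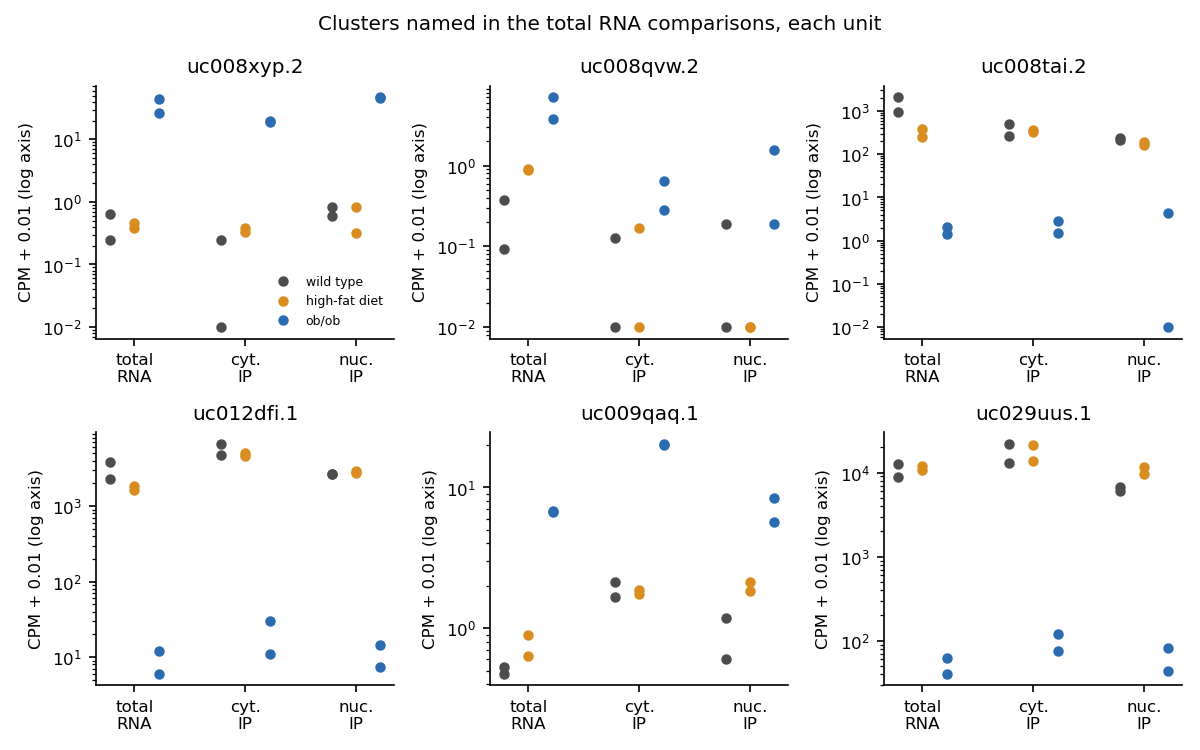
CPM of the 6 clusters named in the total RNA comparisons, in each unit (points, 2 per group) of total RNA, cytoplasmic IP and nuclear IP, on a log axis after adding 0.01. In total RNA the ob/ob units lie apart from both other mouse groups in each panel, above them for uc008xyp.2, uc008qvw.2 and uc009qaq.1 and below them for the rest.

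Cytoplasmic hnRNPK IP was compared with total RNA to find RNAs over-represented with hnRNPK in the cytoplasmic extract. Of 13516 clusters, 10430 passed the threshold, 4860 higher and 5570 lower in the IP. With at least a 2-fold estimate, 2727 were higher and 3553 lower. Cluster uc008ruq.1 (690 nt) had 5258 counts in the 6 IP units and 0 in total RNA, so it was at least 12707-fold higher. Cluster uc008kht.1 (305 nt) had 67559 counts against 1, a ratio of 489806 (95% interval 87907 to 19346578). The 1 count came from high-fat diet replicate 1, and without it the bound is at least 136182-fold. Cytoplasmic IgG had 41.2 and 62.9 CPM of these clusters, against 73.2 to 123 and 704 to 1949 in the IP units. Among lower clusters, uc008tbo.3 had 1459 counts in IP against 1546517 in total RNA, 146-fold lower (95% interval 139 to 154). Its log2 fold change was -6.76 in wild type and -6.14 in high-fat diet, while ob/ob had 0 counts in IP and 14.1 and 31.6 CPM in total RNA. Cytoplasmic IgG had 486 CPM of uc008tbo.3, against 37.6 to 58.9 in the IP units of wild type and high-fat diet. Its cluster number is 18957. In wild type, uc029uus.1 (18954) had 12962 and 21880 CPM in cytoplasmic IP against 8769 and 12630 in total RNA. There uc012dfi.1 (18955) was likewise higher and uc008tai.2 (18950) lower. Whether reads were divided among these clusters was not tested. Cluster uc029ryu.1 had 2 counts in IP against 2726 in total RNA, 188-fold lower (95% interval 52.0 to 1553). Both counts came from high-fat diet IP replicate 2, and without it the bound is at least 106-fold. There were 19 clusters with 0 to 3 total RNA counts and a mean over 5 CPM in IP, each with 1 isoform and with a median length of 400 nt. Of these, 17 also had counts in nuclear IgG. Without composition scaling, by library size only, the split moved to 2920 higher and 7321 lower, around a median of -0.62 in place of -0.11.

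Nuclear hnRNPK IP was compared with total RNA in the same way. Here 10094 clusters passed, 4354 higher and 5740 lower. Cluster uc007czl.1 (615 nt) had 6551 counts in IP and 0 in total RNA, at least 21832-fold higher, and uc008kht.1 had 21331 against 1, a ratio of 213261 (95% interval 38272 to 8423764), or at least 59294-fold without high-fat diet total RNA replicate 1. Nuclear IgG had 115 CPM of uc007czl.1 and 148 of uc008kht.1, against 138 to 177 and 375 to 630 in the IP units. Clusters uc007noh.1 and uc009ngp.1 had 0 counts in the 6 nuclear IP units against 28548 and 18178 in total RNA, at least 952-fold and 606-fold lower. By library size only, 2855 were higher and 6987 lower, around a median of -0.54 in place of -0.18, and without the most counted cluster 4628 were higher and 5416 lower. Estimates of 0 for a whole fraction depend on how reads were divided among overlapping transcripts.

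The nuclear and cytoplasmic IPs were then compared directly. Of 13516 clusters, 8735 passed, 4192 higher in the nuclear IP and 4543 higher in the cytoplasmic IP. Cluster uc008spx.1 (275 nt) was higher in the nuclear IP by 5.11 ± 0.33 on the log2 scale (SE, edgeR adjusted p = 4.6e-09). Cluster uc007upr.1 (557 nt) had 5009 counts in the nuclear IP against 386, a ratio of 17.9 (95% interval 16.1 to 19.9), or 60.8 without wild-type cytoplasmic IP replicate 2. Its log2 fold change was 2.33 in wild type and 5.93 in high-fat diet. In ob/ob the cytoplasmic IP had 0.453 and 0 CPM. Over all mouse groups it moved from 5.62 to 8.89 without high-fat diet cytoplasmic IP replicate 2, 7.71 without ob/ob replicate 1 and 6.24 without wild-type replicate 2. Nuclear IgG had 176 CPM of this cluster, against 90.7 to 190 in the nuclear IP units. Clusters uc009mzj.1 and uc009nqk.1 had 2424 and 1129 counts in the cytoplasmic IP and 0 in the nuclear IP, at least 586-fold and 273-fold lower in the nuclear IP. By library size only the median was 0.11 in place of -0.04, with 4542 higher and 3645 lower in the nuclear IP. Without the most counted cluster 4568 were higher and 4217 lower, so the larger side depends on the scaling. Against total RNA, 2891 clusters were higher in both IPs, 3949 lower in both and 1431 opposite. Independent lists would share 1566 and 2365, and simulations of unchanged IPs gave 0 and 0. With the total RNA units split between the comparisons, 2537 or 2497 clusters were higher in both and 3458 or 3413 lower in both. The covariance of the fold changes was 2.39, against 0.0303 simulated, and 2.40 or 2.37 with split totals.

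The IgG libraries show which RNA the control beads held, with 1 library per compartment and so no test of IP against IgG. CPM are shares of a library, so these values compare composition and not the amount of RNA held. Of the 4860 clusters higher in cytoplasmic IP than in total RNA, 3543 (72.9%, 95% interval 71.6 to 74.1) lay above IgG in all 6 IP libraries, against 41.4% of clusters not called. In the nucleus 1945 of 4354 did (44.7%, 43.2 to 46.2), against 17.7% of clusters not called. If IgG were exchangeable with the IP libraries, 14.3% of clusters picked without regard to these libraries would. The raised clusters were picked because the same IP libraries were high, so 14.3% is no baseline for their share. At least 2-fold above IgG in all 6 libraries were 1796 of the raised clusters in the cytoplasm (37.0%) and 156 in the nucleus (3.58%), against 23.7% and 2.05% of clusters not called. Across clusters, the nuclear IgG fold over total RNA had Pearson's r of 0.799 with the nuclear IP fold, using different total RNA units for each. In the cytoplasm r was 0.367, and it was 0.681 among the 3189 clusters with a mean log2 CPM of 5 or more. By library size only, 46.4% of the raised clusters lay above IgG in the cytoplasm and 6.36% in the nucleus. With the calls made by library size as well, 56.5% and 8.20% lay above IgG. At least 2-fold above it were then 23.8% and 0.911%, against 20.0% and 1.17% of clusters not called.

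**Figure D3:**
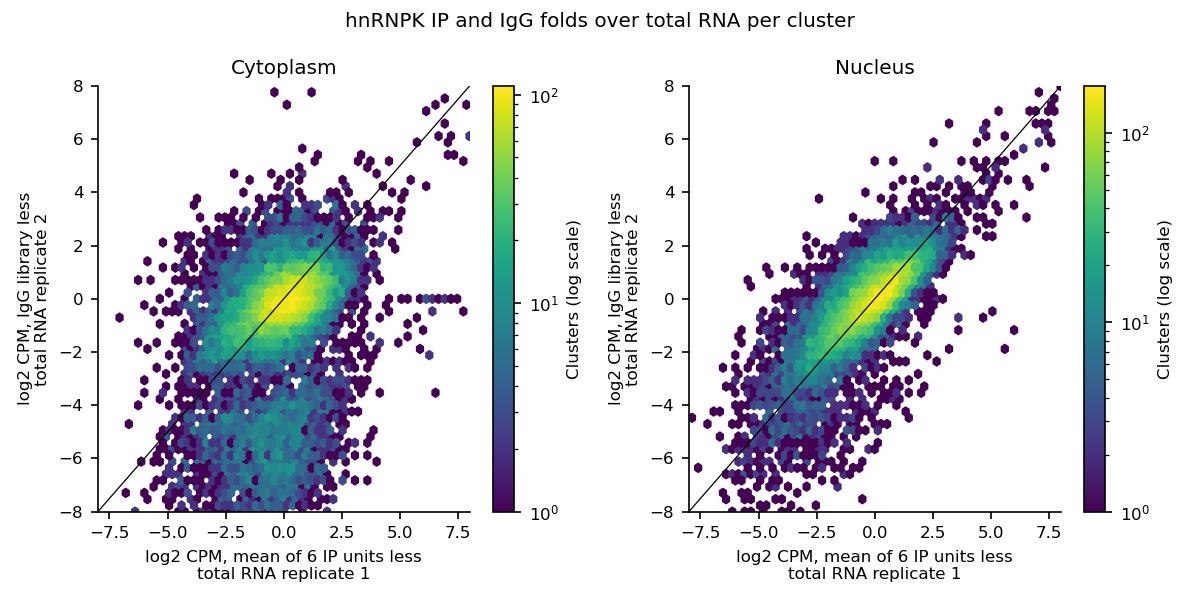
Log2 CPM differences per cluster of the IP mean less total RNA replicate 1 (x axis) and of the IgG library less total RNA replicate 2 (y axis), for cytoplasm (left) and nucleus (right), with colour for the number of clusters and a line at equality. Axes stop at 8 on either side of 0. The nuclear cloud follows the line (r = 0.799), while the cytoplasmic cloud is wider (r = 0.367) and its lower part holds clusters with few counts in the shallow IgG library.

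Fold over total RNA was related to the length of the cluster. In cytoplasmic IP, clusters under 500 nt had a median log2 fold of 1.77 ± 0.30 (SD of the medians of 6 units), and those of 8000 nt or more -0.84 ± 0.23. In the first class 81.6% of 190 clusters were higher and 4.2% lower. In the last class 8.4% of 403 were higher and 73.2% lower. In nuclear IP the medians of these classes were 1.08 ± 0.27 and -0.46 ± 0.10. Spearman's rho with length across 13516 clusters was -0.391 for cytoplasmic IP, -0.148 for nuclear IP and 0.301 for nuclear against cytoplasmic IP. For IgG over total RNA it was -0.061 in the cytoplasm and -0.051 in the nucleus. Among clusters above the median expression the IgG values were -0.161 and -0.028, and among those with a mean log2 CPM of 5 or more -0.200 and 0.0044. In these sets, in that order, cytoplasmic IP had -0.421 and -0.415, and nuclear IP had -0.129 and -0.085. Across all 13516 clusters, each of the 5 relations had a permutation p of 1e-05, the smallest that the permutations can give, and an adjusted p of 1e-05. The permutations take clusters as independent and do not measure the spread between libraries. For nuclear IgG the permutation p was 0.023 above the median expression and 0.81 among clusters with a mean log2 CPM of 5 or more. In single units rho was -0.448 to -0.298 in cytoplasmic IP and -0.192 to -0.069 in nuclear IP.

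**Figure D4:**
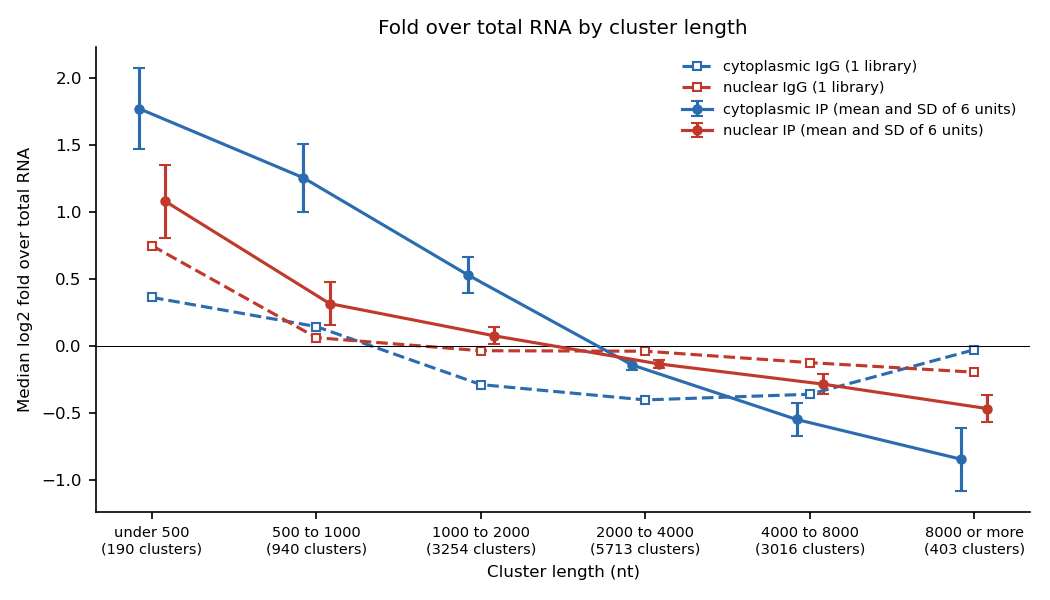
Median log2 fold over total RNA (y axis) by class of cluster length in nt (x axis), as the mean and SD of 6 units for each IP (filled points) and as 1 library for each IgG (open squares). Cytoplasmic IP falls from 1.77 in the shortest class to -0.84 in the longest.

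Whether enrichment over total RNA differed between mouse groups was tested as a difference of differences. In the cytoplasm 1 of 13516 clusters passed for ob/ob against wild type and 1 for high-fat diet against wild type, both times uc007noh.1, higher than in wild type. In the nucleus 2 clusters passed for ob/ob, uc008qml.1 and uc008mqj.1, and 4 for high-fat diet, among them uc009fkv.1 and uc008dcz.2. All were higher in this main fit with edgeR. At an unadjusted p under 0.05 there were 1668, 1336, 1692 and 1426 clusters in these 4 tests, in the order given, and DESeq2 called 422, 252, 353 and 244. Of these 256, 200, 172 and 150 were higher and 166, 52, 181 and 94 lower. By library size only the counts were 1, 1, 0 and 0, and the median for high-fat diet moved to -0.21 in the cytoplasm and -0.57 in the nucleus. With the size factors of DESeq2 a second cluster passed in the cytoplasm of ob/ob, and it was lower. With a replicate block, which the main fit leaves out, 32, 1, 7 and 17 passed with edgeR, of which 12, 1, 4 and 15 were higher.

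In the cytoplasmic IP of wild type, uc007noh.1 had 0 counts, against 955 in ob/ob and 208 in high-fat diet, at least 267-fold and 73.3-fold higher. With 1 wild-type IP unit left out the bounds were 130 or 138 and 35.6 or 37.8. Its total RNA levels were 50.5 to 59.1 CPM in the units of all mouse groups. This cluster also had 0 CPM in every nuclear IP unit and in both IgG libraries. Such estimates of 0 depend on how reads were divided among overlapping transcripts. In the nuclear IP, log2 differences in ob/ob were 5.08 ± 0.73 (SE, edgeR adjusted p = 0.043) for uc008qml.1 and 1.61 ± 0.23 for uc008mqj.1. The first rests on 5 counts in wild type against 110 in ob/ob, a ratio of 33.5 (95% interval 13.9 to 105). It was 3.92 without wild-type IP replicate 1 and no longer called (edgeR adjusted p = 0.12). Without wild-type IP replicate 2 wild type had 0 counts. For high-fat diet the differences were 1.71 ± 0.24 for uc009fkv.1 and 1.71 ± 0.23 for uc008dcz.2 (edgeR adjusted p = 0.024). Nuclear IgG had 87.3 CPM of uc008mqj.1, 15.0 of uc009fkv.1 and 21.5 of uc008dcz.2, above both wild-type nuclear IP units (50.6 and 43.2, 13.9 and 10.8, 11.4 and 10.2). It had 1.17 CPM of uc008qml.1. In the nuclear IP of high-fat diet, uc008mqj.1 had 133 and 129 CPM, above the 118.9 and 119.3 of ob/ob, so its higher level was not particular to ob/ob. For the cytoplasm of ob/ob, 20 clusters passed without wild-type IP replicate 1, 3 higher and 17 lower, and 2 without wild-type IP replicate 2, both higher. For high-fat diet 2 passed without either, 1 higher and 1 lower without replicate 1 and both higher without replicate 2. For the nucleus of ob/ob, 0 passed without either ob/ob total RNA unit, without ob/ob IP replicate 1 or without wild-type total RNA replicate 1. There 1 passed without ob/ob IP replicate 2, a lower one, so that both named clusters lost their call, 1 higher without wild-type IP replicate 2, and 4 without wild-type total RNA replicate 2. For the nucleus of high-fat diet, 0 passed without any of its own total RNA or IP units or without wild-type IP replicate 2. There 1 passed without wild-type total RNA replicate 2 and 8 without wild-type total RNA replicate 1.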

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

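The comparisons of IP with IgG, the test without the most counted cluster and the test of length in IgG were chosen after the results were seen. The splits of the samples and the test of isoform length were set before their results were seen.

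Differences between mouse groups in enrichment over total RNA passed an interaction test for few clusters. In the cytoplasm it was 1 cluster for ob/ob and 1 for high-fat diet, uc007noh.1 both times. It was at least 267-fold and 73.3-fold above wild type in the IP, where wild type had 0 counts. That estimate of 0 depends on how reads were divided among overlapping transcripts. In the nucleus 2 clusters passed for ob/ob, with uc008qml.1 at a log2 difference of 5.08, on 5 counts in wild type, and uc008mqj.1 at 1.61. The nuclear IP level of uc008mqj.1 was also above wild type in high-fat diet. For high-fat diet 4 passed, with uc009fkv.1 and uc008dcz.2 both at 1.71. Among total RNA libraries, the first library of ob/ob replicate 1 stood apart from the other 3 of ob/ob, with 13906 clusters at 10 counts or more. It was also the shallowest total RNA library, and it was 1 such case in 12 checks, where chance gives about 1 in 20.

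The first pattern is the difference between nuclear IP and total RNA. With nuclear and total RNA units reassigned within mouse groups, 1 of 100 splits, the real one, gave as many calls (10742, highest other 5128). This used a fit of only the groups compared, with 15176 clusters. The other splits mix IP and total RNA units in a group or reverse a mouse group. A difference between these kinds of library thus fixes the outcome, so the splits cannot decide whether chance played a part. Distortion of the scaling by the most counted cluster moves every cluster alike and is excluded as the whole cause: without that cluster, 31.83% of clusters lay over 2-fold, by more than 2 SE, from the common shift that left fewest, 1638 higher and 2637 lower. Also open is RNA that beads with any antibody hold. The nuclear IgG fold followed the IP fold with r = 0.799, with no total RNA unit in common. Of raised clusters, 3.58% lay at least 2-fold above IgG in all 6 libraries, against 2.05% of those not called. Some or much of the nuclear difference may therefore come from fractionation and beads. CPM are shares of a library and do not show how much RNA the IgG beads held, so that part cannot be sized. No biological explanation was tested, since the design holds no total nuclear RNA.

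The second pattern is the difference between cytoplasmic IP and total RNA. In a fit of only the groups compared (15117 clusters), 1 of 100 splits, the real one, gave as many calls (11312, highest other 6574). For nuclear against cytoplasmic IP (12502 clusters) it was likewise 1 of 100 (8191 calls, highest other 2908). For the same reason as above, these splits cannot decide whether chance played a part. RNA held by IgG beads cannot be told apart from RNA held by hnRNPK. Among abundant clusters 32.6% of those raised lay at least 2-fold above IgG in all 6 libraries, against 3.65% of those not called (12.2% and 1.2% by library size only, for the calls too), while r with IgG was 0.681. It stays open because the IgG library is single and shallow.

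The third pattern is the higher level of shorter clusters in cytoplasmic IP. A trend of RNA on any beads cannot be told apart from one of the IP: among abundant clusters rho with length was -0.200 for IgG and -0.415 for IP, and the IgG value rests on 1 library. Loss of longer molecules remains a candidate explanation. Within 3394 clusters with several isoforms, the log2 ratio of mean isoform length of IP to total RNA was -0.016 ± 0.0017 (SD of the medians of 6 units), below 0 in 6 of 6 units (exact p = 0.031, two-sided, the smallest possible). The shift is small beside the trend between clusters, and the nuclear IP, with a weaker trend, had a shift of -0.0203 ± 0.0006. The design gives no group for a biological explanation, and none was tested.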

How the results depend on the processing

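The fits without the most counted cluster, those in abundant clusters, those with wild-type units apart and the calls by library size against IgG were chosen after the data were seen. Of 218 alternative values of main results, 143 stayed within their limits, 74 moved and 1 changed sign near 0; of 539 values of named clusters, 484 kept direction and call, 55 kept only direction and 0 reversed. Of 26 named results, 14 passed in every setting. These were the results of the IP comparisons and uc007noh.1 in the cytoplasmic enrichment differences, where wild-type IP had 0 counts. The other 12 lost their call at least once, and they were all those named in total RNA and in the nuclear enrichment differences. Unless stated, the cause was not tested. Results are given for total RNA in the order ob/ob against wild type, high-fat diet against wild type and ob/ob against high-fat diet, and for enrichment differences in the order cytoplasm ob/ob, cytoplasm high-fat, nucleus ob/ob and nucleus high-fat.

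DESeq2 called 2129, 313 and 1433 clusters in total RNA and 422, 252, 353 and 244 enrichment differences. With each library as its own replicate, which would hold if the second number in the titles marked separate samples, 5777, 2001 and 4885 passed, and with all 18 units in the fit 450, 6 and 147. By library size only, 91 passed for ob/ob against wild type, 49 for ob/ob against high-fat diet and 0 for both nuclear differences. Without a filter the ob/ob counts were 387 and 144, and 2 and 10 for the high-fat differences. A filter of 5 CPM gave 2 for cytoplasm ob/ob and 7 for nucleus high-fat. DESeq2 size factors gave 2 for cytoplasm ob/ob. Run 1 only gave 2 for high-fat diet against wild type, and run 2 only gave 133 for ob/ob against high-fat diet and 2 for nucleus high-fat. With only the groups compared in the fit, 0 passed in both nuclear differences. A 2-fold test left 4791, 4570 and 2620 calls for cytoplasmic IP, nuclear IP and nuclear against cytoplasmic IP, since it asks for a larger change. Without the most counted cluster these were 10385, 10044 and 8785. With ob/ob and high-fat diet each against its own wild-type unit, 102 (57 higher, 45 lower, with 38 more opposite) or 1 calls were shared, against 0.

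Leaving out each unit in turn gave 0 to 3221, 0 to 1175 and 0 to 12 calls in total RNA, 10053 to 10461 for cytoplasmic IP, 9742 to 10130 for nuclear IP and 8298 to 8634 for nuclear against cytoplasmic IP. Enrichment differences gave 1 to 20, 1 to 2, 0 to 4 and 0 to 8. A lone sample is here assumed to vary like the other groups.

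The labels give groups the same replicate numbers without saying what they share. Deviations of same-numbered units had r of 0.35 to 0.41 in wild type, 0.26 to 0.32 in ob/ob and -0.12 to 0.09 in high-fat diet. The main tests therefore did not take the numbers to pair samples. Unit pairs in the naming rule, length values per unit and the isoform length shift were still formed from units with the same number. With the replicate block, 63 (23 higher), 0 and 33 (9 higher) clusters passed in total RNA, with uc008qvw.2 at an edgeR adjusted p of 0.059, and 32 (12 higher), 1 (higher), 7 (4 higher) and 17 (15 higher) enrichment differences. The block gave 10877, 10511 and 9108 calls for the IP comparisons.

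The share of raised clusters above IgG was 46.4% in the cytoplasm and 6.36% in the nucleus by library size only, and 80.8% and 60.5% in abundant clusters. With the calls also made by library size it was 56.5% and 8.20%, and 58.1% and 7.78% in abundant clusters. The relation of length with nuclear IgG was not seen in abundant clusters, with rho of 0.0044 (permutation, adjusted p = 0.81). Gene lists, their estimated correlation and C content by region were not run, for want of gene symbols. The shallow cytoplasmic IgG library, with 338469 counts, limits each statement on cytoplasmic background.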

Other observations

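All tests in this part were chosen after related values had been seen.

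Clusters changed in ob/ob total RNA were also followed in the IP libraries. Of the 244 called, 233 were tested in IP. The direction was the same in cytoplasmic IP for 219 (93.99%, 95% interval 90.1 to 96.7) and in nuclear IP for 218 (93.56%, 89.6 to 96.4), against 65.3% and 66.4% of all clusters. The median change was 1.17 on the log2 scale in total RNA, and 1.18 and 1.12 in the same direction in the IPs. RNA bound in the extracts may therefore follow the total level for these clusters. Both IPs share no library with total RNA, but the calls and the IP units may come from the same livers.

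Called clusters often had adjacent cluster numbers in the files. Among the 244 there were 17 neighbouring pairs, against a mean of 2.71 in random draws (95% range 0 to 6, highest 13, permutation p = 1e-05, the smallest possible). Neighbouring numbers may mark related or overlapping transcripts whose reads were divided between them, so such calls may not be independent. The files hold no coordinates with which to test this. Among the named clusters, uc029uus.1 and uc012dfi.1 have the adjacent numbers 18954 and 18955, with uc008tai.2 at 18950 and uc008tbo.3 at 18957.

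Mouse groups were also compared inside each IP, without total RNA, so differences in RNA level are included. For ob/ob against wild type 1726 clusters passed in cytoplasmic IP (803 higher, 923 lower) and 1855 in nuclear IP (743 and 1112). For high-fat diet 250 (130 and 120) and 726 (302 and 424) passed. In the same fit of all 18 units, total RNA had 450 and 6. With 1 unit left out, ob/ob had 375 to 1213 calls in the cytoplasm and 389 to 1680 in the nucleus, the lowest without ob/ob replicate 2 both times. High-fat diet had 10 to 377, the lowest without its replicate 2, and 64 to 340, likewise. Without composition scaling the counts were 614 (435 higher, 179 lower) and 590 (378 and 212) for ob/ob, and 23 (8 and 15) and 1668 (65 and 1603) for high-fat diet, so the larger side depends on the scaling.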
